A study of Mus musculus with 6 samples.

How the data were processed

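Gene expression was measured on 6 Affymetrix arrays of mouse URE cells, a leukaemia line, with 3 arrays from cells carrying a control hairpin against luciferase (shControl) and 3 from cells carrying a hairpin against Hlx (shHLX). Per the labels' protocols, the hairpins were delivered with a lentiviral vector that also encodes a green fluorescent protein, fluorescent cells were sorted, and 10 ng of RNA was amplified with the Nugen Ovation Pico system before labelling. The deposited values are log2 signals of probe sets, 1 column per array. The submitters' processing notes name RMA, which corrects the background, equalises the distributions of the arrays and summarises probes into a log2 value per probe set, and Affymetrix Power Tools 1.178. The genome build and probe set definitions are not given in the sources used here, so no coordinates are printed. No detection or background values were used here, so it is unknown which dim probe sets lie above background, and a fold of a gene that is dim in 1 group is a ratio of signals that tends to understate a change in RNA.

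Of 35556 probe sets, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several and 12146 were not listed there. By Entrez identifier, 21698 of the probe sets with 1 symbol matched the mouse RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for which genes neighbour each other. Probe sets with several symbols or none entered no main test. A gene with several probe sets (999 genes) took the one with the highest mean over the 6 arrays, which left 19938 genes, with no filter on dim signal.

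The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings, no covariates, two-sided), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. Hlx itself was also tested with an exact permutation test of the difference of the means. Values are given as mean ± SD of the log2 signal, folds with limma's 95% confidence interval, and n is the number of arrays. The number of arrays limits the precision, and the SD between replicates was 0.0728 for the median gene. Whether the replicates came from separate transductions or cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

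A total of 34 gene lists were fixed for myeloid maturation, proliferation, stress, signalling and the markers of other cell types, and 768 of their 890 entries had a probe set of their own. The lists were chosen with URE taken as a PU.1-deficient myeloid leukaemia line, in both groups alike. The 32 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. With an estimated correlation, camera also refers each list to the 4 residual degrees of freedom, which by itself makes a call harder. Of the remaining lists, the 15 mitochondrially encoded genes had no probe set under their names, and the list of Hlx, Btg1 and Pak1 was read gene by gene. Btg1 and Pak1 were recalled from the publication on this series, so they are not independent of these arrays. Pak1 had no probe set under its name in the annotation and was not analysed here.

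Genes were named by a rule: Hlx, Btg1 and Pak1, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p. Predicted or unnamed models and olfactory, vomeronasal and small RNA genes were passed over for naming and kept in every test. The rule, the lists, the tests and the alternatives were set before the data were examined. Other genes named below were chosen after their values were seen.

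The alternatives were a second quantile normalization, centring of each array on its median, filters at the 25th percentile and at the median of mean signal, an intensity trend or a robust prior in the variance model, array weights, the mean of a gene's probe sets, all probe sets tested, an adjusted p under 0.10, a fold of at least 1.5, a test without variance moderation, the replicate number as a block, and leaving out each array in turn. The code was tested on simulated data for the 19938 genes, with 50 genes changed at each size. It recovered 34% of genes changed by 0.3 on the log2 scale, 90% at 0.6, 98% at 1 and 100% at 2, and called 4 unchanged genes. In the simulation 2 gene lists were shifted as well, and the noise of each gene was drawn independently. Far fewer genes were changed than were called on the real arrays. These shares therefore check the code and may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.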

Results

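Transcript levels were compared between URE cells carrying a hairpin against Hlx, which encodes a homeobox transcription factor, and cells carrying a control hairpin against luciferase. The study set out to examine the part that Hlx plays in blood cell differentiation and in leukaemia. Each group had 3 arrays. The 6 arrays had nearly equal distributions, with medians from 7.02 to 7.10 on the log2 scale. Correlations across all genes tested were 0.9943 to 0.9969 within groups and 0.9919 to 0.9952 between groups. The first principal component held 59.4% of the variance and separated the groups. The second held 18.1% and crossed the groups. It set shControl 1 (9.53) and shHLX 3 (9.10) apart from the other arrays (-9.04 to -0.64). The labels name no batch, so its cause was not tested.

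Hlx mRNA differed little between the groups. Its probe set (10360834, Entrez gene 15284) gave 10.18 ± 0.048 (SD, n = 3) on the shControl arrays and 10.10 ± 0.056 (SD, n = 3) on the arrays labelled shHLX. The shHLX signal was 95.1% of control (95% confidence interval 87.8% to 103%). The individual values were 10.21, 10.12 and 10.20 with the control hairpin and 10.08, 10.06 and 10.17 with the Hlx hairpin, so the groups overlapped. The difference of -0.07 did not pass an exact two-sided permutation test (p = 0.2, where 3 arrays against 3 can give 0.1 at the smallest) or limma (adjusted p = 0.479). The arrays therefore do not show the knockdown that the labels name, and the direction of every comparison here rests on the labels alone.

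Btg1, which encodes a protein that restrains proliferation, rose from 11.15 ± 0.033 (SD, n = 3) with the control hairpin to 12.03 ± 0.011 (SD, n = 3) on the arrays labelled shHLX. This was a 1.84-fold rise (95% confidence interval 1.72 to 1.96, limma adjusted p = 2.07e-05), and all 3 shHLX values lay above all 3 control values. Btg1 was recalled from the publication on these arrays and is no independent evidence.

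**Figure D1:**
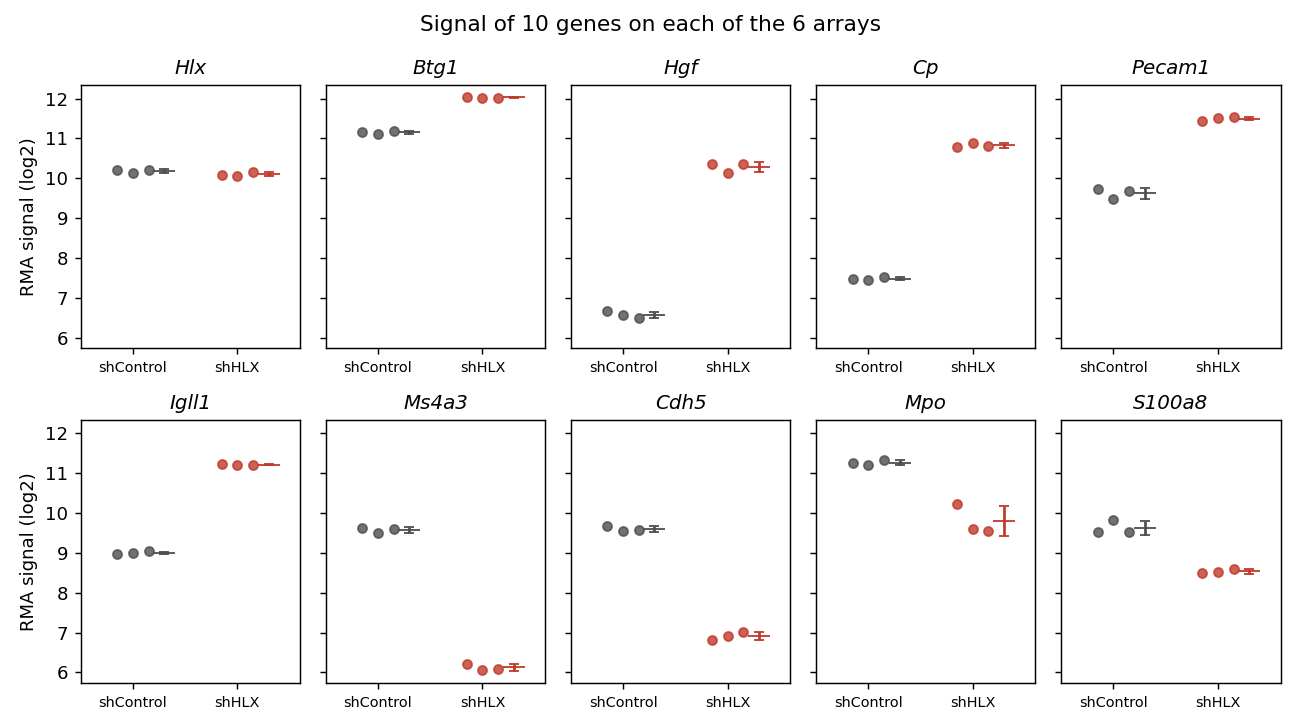
The vertical axis is the log2 RMA signal and each point is 1 array, with bars for the mean and SD of the 3 arrays of a group. Hlx overlaps between the groups near 10, while Btg1, Hgf, Cp, Pecam1 and Igll1 are higher and Ms4a3, Cdh5, Mpo and S100a8 are lower on every array labelled shHLX.

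The largest rise was that of Hgf, the hepatocyte growth factor, from 6.57 ± 0.085 (SD, n = 3) to 10.29 ± 0.12 (SD, n = 3), or 13.2-fold (95% confidence interval 11.7 to 14.8, limma adjusted p = 2.66e-07). Cp, which encodes the copper-carrying ferroxidase ceruloplasmin, rose 10.2-fold (9.42 to 10.9), and the transporter gene Abca9 rose 9.12-fold (8.22 to 10.1). Cyyr1, the metalloreductase gene Steap2, the mRNA decay factor gene Zfp36l1, Zcwpw1, Xlr, the DNA sensor gene Aim2 and Cd200r4 rose between 8.64-fold and 4.94-fold. The largest fall was that of Ms4a3, a gene of granulocyte and monocyte progenitors, from 9.57 ± 0.066 (SD, n = 3) to 6.12 ± 0.086 (SD, n = 3), a log2 change of -3.45 (SE 0.06, limma adjusted p = 2.02e-07). Cdh5, which encodes the endothelial cadherin, fell by 2.68 on the log2 scale (SE 0.07, limma adjusted p = 6.66e-07).

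Further falls were those of Tspan12 (-2.19), Zfp462 (-1.91), the Wnt receptor gene Fzd3 (-1.71), Ifitm1 (-1.50), the myeloperoxidase gene Mpo (-1.46), Serpinb10 (-1.44), Ces1d (-1.41) and Ifitm7 (-1.40), all as log2 changes. Mpo varied most of these between the shHLX arrays, at 10.22, 9.61 and 9.56 against 11.20 to 11.33 in the controls. All 20 of these largest changes passed limma whichever array was left out. Xlr, Fzd3, Mpo, Serpinb10 and Ces1d did not pass a test without variance moderation, which 15 of the 20 did.

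Across the 19938 genes, 748 were higher and 485 were lower on the arrays labelled shHLX (limma, adjusted p under 0.05), or 6.18% of the genes. Most changes were small: the median called gene moved 1.27-fold upwards or 1.26-fold downwards, 260 of the 1233 moved at least 1.5-fold and 78 at least 2-fold (56 higher and 22 lower). The groups did not overlap for any called gene, and for 26.15% of all genes, where chance gives 10%. The count fell to 806 without shControl 2, 698 without shControl 3 and 766 without shHLX 1. It was 197 in a test without variance moderation, and 2261 with an intensity trend in the variance model.

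**Figure D2:**
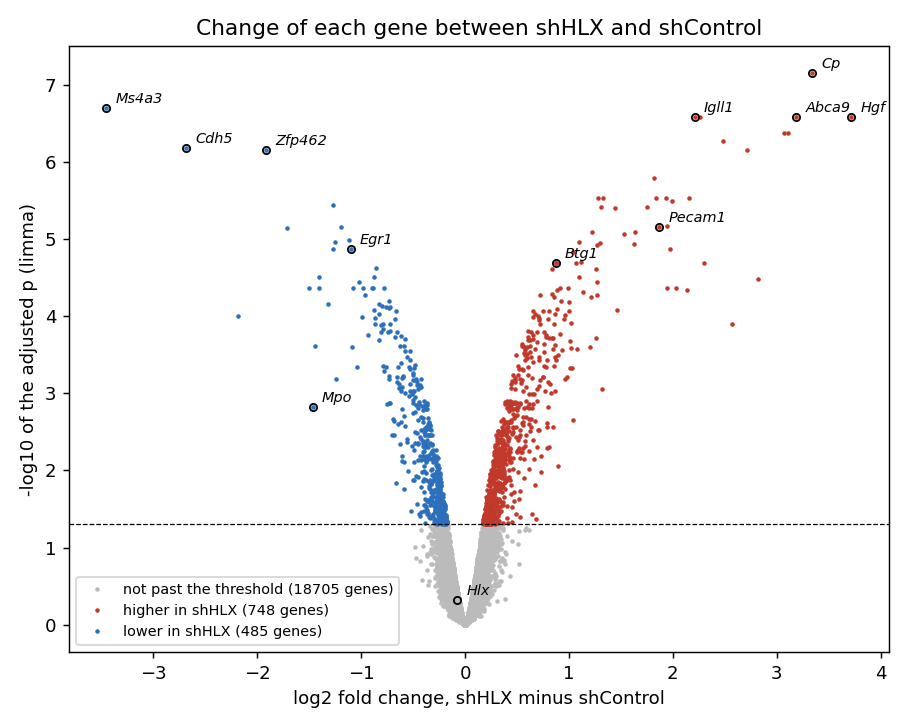
The horizontal axis is the log2 fold change of each gene (shHLX minus shControl), the vertical axis is -log10 of the adjusted p from limma, and the dashed line marks the threshold of 0.05. Of the 19938 genes, 748 are higher and 485 lower, and Hlx lies below the line at -0.07.

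Genes of granulocyte and monocyte maturation moved in both directions. Of 14 genes of primary granules and of the progenitor stage that makes them, Ms4a3 and Mpo fell while the surface receptor genes Clec12a (1.69-fold) and Igsf6, Ctsc (1.34-fold) and Hp rose, and 8 did not pass (5 higher and 3 lower adjusted over the list alone). The genes of the abundant granule proteases were not called, with log2 changes of -0.05 for Elane, -0.10 for Prtn3 and -0.01 for Ctsg. The list was not called by camera (adjusted p = 0.984), whose direction was up while the median (-0.03) and mean (-0.25) were negative. By fry, which tests the average change of the members and can be carried by a few large ones, it was called downwards (adjusted p = 0.00146, against 0.984 by camera). The large falls of Ms4a3 (-3.45) and Mpo (-1.46) stood against 4 called members that rose. The fry call therefore does not describe the typical member, as the median of -0.03 shows. Igsf6 was lost when any 1 array was left out (adjusted p 0.0541 to 0.131).

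Of 27 mature neutrophil genes, 4 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.699). S100a8, which encodes a calcium-binding protein of neutrophils, fell by 1.09 on the log2 scale, and Cd24a (-0.96), Lrg1 (-0.85), Cebpe (-0.73) and Trem1 (-0.42) were also lower. Itgam (1.68-fold), Anxa1, Lcn2 and Cxcr2 rose, of which Cxcr2 was lost when any 1 array was left out (adjusted p 0.0587 to 0.101). Of 25 monocyte and macrophage genes, Emb (1.75-fold), Lgals3 (1.46-fold), the lysozyme gene Lyz2 (1.31-fold) and Cybb rose, and the receptor gene Csf2ra fell by 0.42 on the log2 scale (6 and 1 adjusted over the list alone, camera adjusted p = 0.464). The median of that list was -0.01 and its mean 0.09. Cybb was lost without shControl 1, shControl 2, shControl 3 or shHLX 3 (adjusted p up to 0.119).

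Among 30 myeloid transcription factor genes, the immediate early gene Egr1 (-1.10), Cebpe, Gfi1 and Cebpd fell and Fosl2 (1.55-fold) and Klf6 (1.39-fold) rose (6 and 7 adjusted over the list alone, camera adjusted p = 0.984). Spi1, which encodes PU.1, differed by 0.00 (SE 0.05). Of 28 stem and progenitor genes, the receptor gene Kit (-0.73), Gfi1 and Lyl1 fell, while the receptor gene Flt3 (1.56-fold) and Hhex rose (5 and 4 adjusted over the list alone, camera adjusted p = 0.62). Hoxb4 (1.5-fold) and Hhex were the called members among 31 Hox and related homeobox genes, both higher, also adjusted over the list alone (camera adjusted p = 0.984). Gfi1 was lost without shControl 3 (adjusted p = 0.0555), Cebpd without shHLX 1 (0.0508), Lyl1 without any of 5 arrays, all but shHLX 2 (up to 0.113), and Hhex without any 1 array (0.0831 to 0.138).

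Targets of p53 were called upwards as a list. Of 23 measured, 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00381). With an estimated correlation the list was not called (adjusted p = 0.478), and the other 18 of 19 alternatives, with adjusted p from 0.00136, called it. The risers were Zmat3 (1.54-fold), Trp53inp1 (1.26-fold), Tnfrsf26 (1.25-fold), Btg2 (1.24-fold), Sesn2 and Aen, while the death receptor gene Tnfrsf10b fell by 0.33 on the log2 scale. The long-known targets Ccng1 (0.04) and Mdm2 (0.10) were not called, nor were Pmaip1 (-0.20), Bbc3 (0.07) and Fas (-0.003). Cdkn1a and Bax, also fixed for this list, had no probe set of their own, so the call does not cover them. Leaving out 1 array ended the calls of Sesn2 (shControl 2, shControl 3 or shHLX 1), Aen (shControl 1, shControl 3, shHLX 1 or shHLX 3) and Tnfrsf10b (any shControl array), with adjusted p up to 0.0714, 0.136 and 0.0678.

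Genes that restrain proliferation were also called upwards as a list. Of 24 measured, 7 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0311, median 0.04, mean 0.10). With an estimated correlation the list was not called (adjusted p = 0.478, in a range of 0.00299 to 0.478 over the alternatives). It was also not called without shHLX 3 (0.0649), on ranks (0.112), or among genes above the 25th percentile (0.0687) or the median (0.157) of signal. This list holds Btg1, chosen from these arrays, and shares Btg2 with the p53 list, so its count is not independent. Btg1, the stress gene Gadd45a (1.47-fold) and Btg2 kept their calls whichever array was left out, while Rb1, Txnip, Mxd4, Ccng2 and the falling Gadd45b (-0.26) did not. Rb1 and Txnip were lost when any 1 array was left out, Mxd4 for each array but shControl 2, Ccng2 for each but shControl 1, and Gadd45b for shControl 1, shControl 3 or shHLX 1. Their adjusted p then reached 0.153, 0.144, 0.127, 0.177 and 0.0729. No measured gene of a cyclin-dependent kinase inhibitor in this list was called over all genes. Their log2 changes were 0.06 for Cdkn1b, -0.05 for Cdkn1c, -0.10 for Cdkn2a, -0.02 for Cdkn2b, -0.18 for Cdkn2c and 0.12 for Cdkn2d. Cdkn1a had no probe set of its own.

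Few cell cycle genes passed the test. Of 29 S phase genes Tk1 (-0.25) and Mcm6 (-0.22) fell (6 lower adjusted over the list alone, camera adjusted p = 0.23), and of 29 G2 and M phase genes the spindle checkpoint gene Bub1b fell by 0.62 on the log2 scale (1 lower adjusted over the list alone, camera adjusted p = 0.894). Among 15 G1 cyclin and kinase genes Ccnd2 rose 1.29-fold and Ccnd3 fell by 0.24 on the log2 scale (2 and 3 adjusted over the list alone, camera adjusted p = 0.839). Of 26 replication-dependent histone genes H4c3 fell, also adjusted over the list alone (camera adjusted p = 0.0713), and that list was called downwards without shControl 2 (adjusted p = 0.0345, with 0.0163 as the lowest of the alternatives that called it). Among 23 apoptosis genes Bid (-0.83) fell and Bcl2l11 rose (1 and 2 adjusted over the list alone, camera adjusted p = 0.984). Leaving out an array ended the calls of Ccnd3 and H4c3 (any of the 6), Tk1 (all but shHLX 2), Mcm6 (all but shHLX 3) and Bcl2l11 (all but shHLX 2), with adjusted p up to 0.106, 0.0868, 0.144, 0.159 and 0.126.

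Of the stress, metabolic and growth lists, camera called 3 upwards. Of 28 genes in a list of Myc, its targets and ribosome biogenesis, the transferrin receptor gene Tfrc (1.28-fold) and the ribosome biogenesis gene Ebna1bp2 rose, also adjusted over the list alone, and camera called the list upwards (adjusted p = 0.0163, and adjusted p = 0.991 with an estimated correlation). Myc itself differed by -0.12 and was not called. Of 24 hypoxia and glycolysis genes, Egln1 and Ddit4 rose and Car9 (-0.53) fell (5 and 1 adjusted over the list alone), and camera called the list upwards (adjusted p = 0.0367, and adjusted p = 0.664 with an estimated correlation). Of 25 genes of the integrated and endoplasmic reticulum stress responses, the amino acid transporter gene Slc7a11 (1.29-fold), Sesn2, Edem1 and Ddit4 rose and the serine synthesis gene Phgdh (-0.61) fell, with 4 and 1 also adjusted over the list alone. Camera called that list upwards (adjusted p = 0.0375, and adjusted p = 0.718 with an estimated correlation).

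These 3 calls depended on single arrays and on other settings. The Myc list was lost without shControl 2 (adjusted p = 0.14) or shHLX 3 (0.0649), over a range of 0.00548 to 0.991. The hypoxia list was lost without shControl 3 (0.112), shHLX 1 (0.0905) or shHLX 3 (0.145), over 0.00835 to 0.664. The integrated and endoplasmic reticulum stress list (stress list) was lost without shControl 1 (0.0583), shControl 3 (0.0593), shHLX 1 (0.051) or shHLX 3 (0.114), over 0.0223 to 0.718. With all arrays kept, fry called none of the 3 (0.0992, 0.0992 and 0.0674), and neither did camera among genes above the median of signal (0.157, 0.289 and 0.36). The hypoxia and stress lists were also lost above the 25th percentile of signal (0.0687 for both), the Myc and stress lists with array weights (0.071 for both), and the latter after a second quantile normalization (0.0638). Ebna1bp2, Egln1, Ddit4 and Edem1 were each lost when any 1 array was left out, with adjusted p up to 0.147, 0.151, 0.189 and 0.0847, and Sesn2 without shControl 2, shControl 3 or shHLX 1 (up to 0.0714). Among 20 cholesterol synthesis genes Hmgcs1 rose 1.36-fold and Tm7sf2 (-0.55) fell, also adjusted over the list alone (camera adjusted p = 0.984), and Tm7sf2 was lost without shHLX 1 (adjusted p = 0.0539). Of 31 interferon-stimulated genes Stat2 rose, 0 passed adjusted over the list alone (camera adjusted p = 0.599), and Stat2 was lost when any 1 array was left out (adjusted p 0.0669 to 0.164). No member passed limma, over all genes or adjusted over the list alone, among 42 ribosomal protein, 35 oxidative phosphorylation and 14 heat shock genes (camera adjusted p = 0.984, 0.62 and 0.502). At an unadjusted p under 0.05 these lists held 2, 3 and 3 genes, and a test without variance moderation called 0, 0 and 1.

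Signalling genes showed changes in single members. None of 26 genes of PAK, RAC and RAS signalling passed limma, over all genes or adjusted over the list alone (camera adjusted p = 0.984), with 3 at an unadjusted p under 0.05 and 0 in a test without variance moderation. Of 26 genes that respond to ERK, Fosl2, the kinase gene Pim1 (1.39-fold), Socs2, Dusp6 and Spry1 rose and Egr1, Etv5 (-0.41) and Fosb fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.984). Of 23 cytokine signalling genes Pim1, Ccnd2 and Socs2 rose and Kit and Csf2ra fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.261). Of 20 adhesion genes, Pecam1, which encodes the adhesion receptor CD31, rose 3.65-fold (95% confidence interval 3.25 to 4.10), Itgam and Itgb2 also rose, and Cd63 (-0.68), Itgal, Cd44 (-0.34) and Icam2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.984). Of 19 Wnt and Notch target genes, Lgr5 (1.63-fold) and Nfkbia (1.23-fold) rose and Nrarp (-0.59) fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.984). Leaving out an array ended the calls of Fosb (shControl 3), Itgb2 (all but shHLX 3), Icam2 (any of the 6) and Nrarp (shControl 2 or shControl 3), with adjusted p up to 0.0663, 0.119, 0.143 and 0.0766.

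No list of markers of other cell types was called. Of 23 lymphoid genes, the surrogate light chain gene Igll1 rose 4.64-fold (95% confidence interval 4.33 to 4.96) and Vpreb3 rose, with 2 and 0 also adjusted over the list alone, while the list was not called (camera adjusted p = 0.984, median -0.04, mean 0.06). Of 20 stromal genes, the smooth muscle actin gene Acta2 rose 1.9-fold and Fbln1 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.984, median -0.04, mean 0.04). In the dendritic cell list (19 measured) Flt3 rose, in the megakaryocyte list (13 measured) Thbs1 rose 1.31-fold, and each was also the count adjusted over the list alone (camera adjusted p = 0.984 for both). In the erythroid list (14 measured) Car2 rose (1 and 1 adjusted over the list alone, camera adjusted p = 0.62). None of 20 mast cell, basophil and eosinophil genes passed limma, over all genes or adjusted over the list alone (camera adjusted p = 0.172), with 3 at an unadjusted p under 0.05 and 0 in a test without variance moderation. Leaving out an array ended the calls of Vpreb3 (shControl 2 or shHLX 1), Fbln1 (all but shHLX 3) and Car2 (all but shHLX 2 and shHLX 3), with adjusted p up to 0.0618, 0.155 and 0.112.

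With an estimated correlation, camera called 0 of the 32 lists, and 2 had an unadjusted p under 0.05. This setting also lowers the degrees of freedom. The antiproliferative list had an estimated correlation of -0.0127, below the preset 0.01, yet its unadjusted camera p rose from 0.00292 to 0.0299. Its loss was therefore not due to a higher correlation between its genes. The preset correlation called 5. Camera on ranks also called 5, without the antiproliferative list (adjusted p = 0.112) and with the replication-dependent histone list (0.0414) in its place. Of the 5, fry called the p53 and antiproliferative lists, and with the primary granule and progenitor list downwards it called 3 lists, while 30 passed fry's test for changes in either direction. Median, mean and camera direction differed in sign for 9 lists, none of them called by camera.

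**Figure D3:**
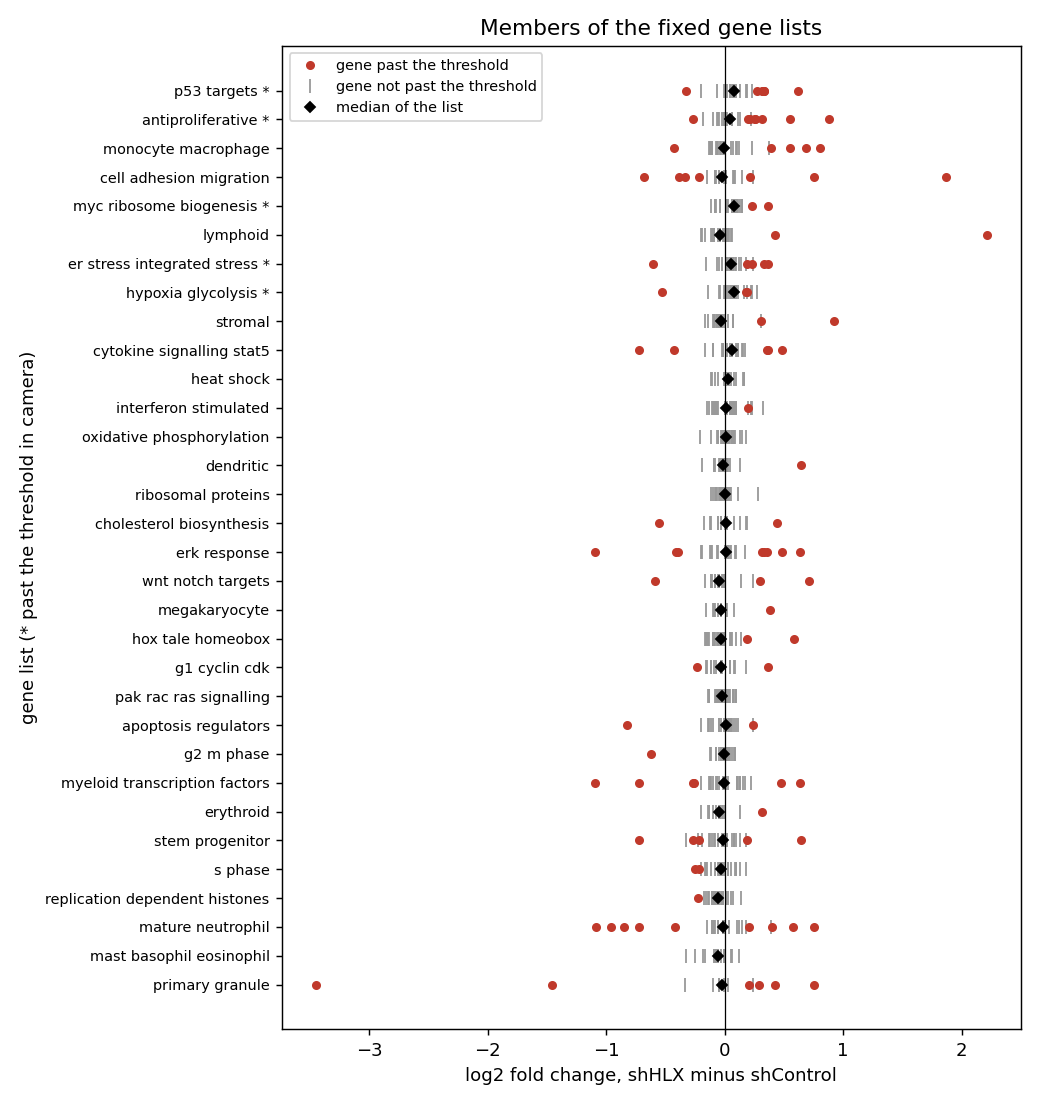
The horizontal axis is the log2 fold change (shHLX minus shControl) of each measured member of the 32 gene lists on the vertical axis. Red points are genes past the threshold, grey ticks are the other genes, diamonds are list medians, and the 5 lists called by camera carry an asterisk.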

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

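Probe sets that entered no main test also held differences between the groups when all probe sets were tested together with limma. Of 12146 probe sets without a listed gene, 33 were higher and 39 were lower on the arrays labelled shHLX, or 0.593% of them, against 3.52% of the 21789 with 1 gene symbol. Of 1621 probe sets with several symbols, 13 were higher and 6 were lower. Probe set 10338822, not listed, gave the largest rise among those without a listed gene, from 5.869 ± 0.079 (SD, n = 3) to 6.847 ± 0.177 (SD, n = 3), a log2 change of 0.978. Probe set 10494023, also not listed, fell from 9.813 ± 0.082 (SD, n = 3) to 7.451 ± 0.047 (SD, n = 3), a log2 change of -2.362. No gene can be given for either here.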

How the results depend on the processing

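Hlx kept its negative sign and stayed short of the threshold under all 17 alternatives run for it (log2 changes -0.10 to -0.05, adjusted p 0.232 to 0.729). All alternatives here were planned. Of 1233 called genes (748 higher and 485 lower), only genes above the median signal gave 2064 (1295 and 769), an intensity trend 2261 (1437 and 824), a fold of at least 1.5 260 (172 and 88) and a test without variance moderation 197 (117 and 80). Testing all probe sets gave 536 higher and 321 lower, which are probe sets and not genes. Filters change which genes are tested and adjusted for; the cause of the other moves was not tested. Leaving out 1 array, which also removes a degree of freedom, gave 698 to 901 (441 to 544 higher and 257 to 369 lower). The replicate number as a block gave 800 (497 and 303), of which 779 were among the 1233. Deviations of same-numbered arrays correlated at -0.17, 0.13 and -0.15, and 0 arrays correlated best with their own number, so the numbers were not read as pairs. Against 5 called lists there were 2 above the 25th percentile of signal and 3 with array weights, all among the 5, 2 above the median (p53 targets and, not among the 5, replication-dependent histones), 0 with an estimated correlation, 3 by fry (2 among the 5) and 1 to 5 without 1 array (1 without shHLX 3). The primary granule and progenitor list (mean -0.25) was called downwards by fry, which asks another question than camera. Of 81 named genes past the threshold, apart from Hlx, 30 passed under every alternative that tested them (the signal filters drop dim genes) and 61 whichever array was left out. Of 56 others picked by the same rule, most not printed here and none past it, 37 passed under at least 1. No named gene reversed while past the threshold. The share of higher calls was 54.3% after quantile normalization and 65.7% after centring, against 60.7%. Of 36 genes past the threshold that were named after their values were seen, 10 passed under every alternative that tested them and 23 whichever array was left out. Genes so named that were not past the threshold are outside this count. No signal over background was used here, so dim genes are the least certain.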

Other observations

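Of the tests below, the counts over other splits of the arrays were planned, and the tests of Hlx, of mixed cells and of neighbouring genes were chosen after the results were seen. Several further genes changed at least 2-fold and were picked for their size after the fact. The myeloid receptor genes Cd33 and C5ar1 rose 4.39-fold (95% confidence interval 3.63 to 5.32) and 4.09-fold (3.42 to 4.89) on the arrays labelled shHLX, and the inflammasome gene Nlrp3 rose 2.4-fold (2.17 to 2.65). Of single genes of secreted proteins, Sfrp1, a Wnt antagonist, rose 4.47-fold, Ccn3 3.98-fold and the semaphorin gene Sema3c 2.71-fold, and Nrp1, which encodes a semaphorin co-receptor, rose 3.94-fold. The amine oxidase gene Maob rose 4.79-fold. Among the falls were Rapgef3 (log2 change -1.27), the small GTPase gene Rhou (-1.25) and the histone deacetylase gene Hdac7 (-1.11). These 11 genes passed limma whichever array was left out, and all but Sfrp1, Nrp1 and Hdac7 also passed a test without variance moderation.

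Called genes and lists were also counted for the other splits of the 6 arrays into 3 and 3. The real split gave 1233 genes, and the highest of the other 9 gave 0 by limma (259 to 2220 genes at an unadjusted p under 0.05), so 1 of 10 splits reached the real count. For lists, the real split gave 5 and the highest other gave 6, with shControl 1, shControl 3 and shHLX 3 on 1 side, so 2 of 10 reached the real count. With 10 splits, no share under 0.05 can be had. Each other split also has arrays of both groups on both sides. The difference between the groups then adds to the spread within a side and lowers the count of called genes. The contrast with the real split is therefore no measure of chance.

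Hlx differed by 5% between groups that differed at 1233 other genes. Arrays exchanged between the groups would not account for this: Hlx lay between 10.06 and 10.21 on all 6 arrays. No regrouping of them gives a group with clearly lower Hlx. By distance, 0 of 6 arrays lay nearer to the other group's mean than to their own. That result largely follows from the 1233 calls, and it could not show a full swap of labels. Falls of 0.5 or more occurred at this signal level about as often as among all genes, which does not exclude a partial compression. Of 1150 genes with a control signal within 0.25 log2 units of that of Hlx, 7 fell by 0.5 or more past the threshold. This was 0.609%, against 0.557% of all genes, where 5 genes were asked for, and Ifitm1 (-1.50) and Hdac7 (-1.11) were among the 7. This test of other probe sets cannot show whether falls are compressed in the Hlx probe set itself. A first form of this test, on the mean of all arrays, which a fall itself lowers, gave 4, and both its reading as undecided and the move to the control signal were set after values were seen. A knockdown lost by the time of harvest, signal from other transcripts in the Hlx probe set, or an effect of the hairpin on other transcripts may play a part, and none was tested.

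Single markers of other cell types were higher on the arrays labelled shHLX, and mixing was tested for Igll1, Vpreb3 and Acta2 but not for Flt3, Thbs1 and Car2, markers of 3 further types. B-lineage cells mixed into those samples would raise their other genes as well, but 11 others had a median log2 change of -0.041 (median absolute deviation 0.077), and Vpreb1, the usual partner of Igll1, was at -0.20. Stromal cells would likewise raise the other 19 stromal genes, whose median was -0.036 (0.07), with Fbln1 the 1 called member. The sort on fluorescence would not remove transduced cells of another type. A change of these genes within the leukaemia cells that comes with the hairpin remains possible and was not tested.

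Called genes often lay next to each other in the mouse gene table. This was noticed while looking at medians per chromosome and at a running mean along chromosomes. Chance placement was set against a permutation test with 10000 shuffles of the calls among genes of like signal: 93 neighbouring pairs changed the same way, against a mean of 44.96 and a maximum of 73 (one-sided p = 1e-04, the smallest the shuffles can give), while pairs of unlike name changed opposite ways were not in excess (33 against 39.1, p = 0.862). Neighbours of like name, such as Cd200r1, Cd200r4 and Cd200r2, account for part, but 83 pairs remained without them (mean 42.86, maximum 71), among them Cfap69 and Steap2, Hgf and Sema3c, and Rapgef3, Slc48a1 and Hdac7. Like names were those sharing their first 3 letters, so related neighbours of other names may remain. Regional differences between the sorted populations, such as the sites where the vector integrated, or transcripts that overlap, are among possible accounts of the rest. Neither was tested, and other accounts remain possible. Btg1, Xlr, Fzd3, Ifitm7, Mpo and Acta2 also lay beside a gene changed the same way. So did Txnip, Mxd4 and Rb1 of the antiproliferative list. Which of these pairs arose by chance cannot be told, and such genes may not all be separate responses.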
